A study of Mus musculus with 18 samples.

How the data were processed

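RNA was taken from forepaws of C57BL/6 mice, WT and Sema3b-/-, with arthritis or as controls. Per the labels, total RNA was purified on columns, barcoded and pooled by CEL-seq, amplified by in vitro transcription and sequenced with paired ends on a NextSeq500. The authors aligned reads with BWA to mm10 and analysed counts with DESeq2 1.32. The counting tool, the gene annotation and whether molecular barcodes were used to remove duplicate reads are not given in the sources used here. The labels give genotype and treatment for each of the 18 samples, and no sample was left out. Replicate numbers follow the titles, except that the titles of Sema3b-/- control replicates 3 and 4 hold different animal numbers and the same inner name, with the number 3, and the second was numbered 4. The column of Sema3b-/- arthritis replicate 5 ends in Ct, while the title and the treatment label of that animal number say arthritis, and it was used as arthritis.

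The table deposited by the authors holds 18585 genes and, for each library, a signal that is a count divided by a size factor (normalized count). Whole reads were recovered from it by finding the factor of each library, within 0.02 of a read for 100% of values, and total reads per library were summed from these. The deposited table also holds, for 6 comparisons, a log2 fold change, a p-value, a score and an adjusted p-value by the authors. These deposited p-values match a t distribution with 14 degrees of freedom. The authors' calls were counted at an adjusted p under 0.05. Names of 26 genes that a spreadsheet had turned to dates were restored.

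The design planned edgeR for counts. Because the file holds normalized counts, limma-trend (limma 3.58.1 in R 4.3.3), planned for a file without counts, was the main test. It was run with robust empirical Bayes on log2 of the value plus 1. The recovered reads also allow count models, which were run as alternatives and differ in places. One model with 4 group means was fitted to all 18 libraries, and contrasts gave 2 arthritis effects, 2 genotype effects, 2 comparisons of both together, and the interaction. Genes with a value of at least 10 in at least 4 libraries were tested, 13809 of 18585, and a call is a Benjamini-Hochberg adjusted p under 0.05. Errors of levels are SD between libraries and errors of log2 fold changes are SE from the fit. Each title holds its own animal number, but the labels do not state outright that each library is from a separate animal. The p-values measure the spread between these libraries. Shares of the normalized counts taken by a list were compared by exact permutation of libraries, two-sided, and adjusted over 24 tests.

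Gene lists were fixed before the data were examined, as were the comparisons, the thresholds, the named gene rule and most alternatives. The lists cover neutrophils, monocytes and macrophages, proinflammatory cytokines, chemokines, matrix proteases and inhibitors, osteoclasts, osteoblasts and osteocytes, cartilage, synovial fibroblasts, complement and acute phase, interferon-stimulated genes, cell cycle, semaphorins and their receptors, oxidative phosphorylation, skeletal muscle, epidermis, erythroid cells, B cells, T and NK cells, adipocytes, endothelium, peripheral nerve, immediate early genes, sex-linked genes and the genes next to Sema3b. Ly6g, Il17a, Flg, Hba-a2, Hbb-bt, Ahsp, Ighm and Lsmem2 are not in the table, and Adgre1, C1s1, Cnmd, Epb42, Hbb-bs and Naa80 were read under older symbols (Nat6 for Naa80). Lists were tested with camera at a correlation of 0.01 between genes, again with the correlation estimated from the data, and with fry, and single members were also adjusted within their list.

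Genes were named by a rule. It takes, in each comparison of 1 factor, the 10 highest and the 10 lowest log2 fold changes among called genes whose level is at or above the median of tested genes, whose groups do not overlap and whose name is not a placeholder. The planned level was CPM (counts scaled to library size), and the normalized value took its place, with a median of 106. Where fewer than 5 genes were called, the 5 with the lowest p are given as values. From each list, the 4 members with the lowest p in WT arthritis were taken, with Sema3b, its neighbours and sex-linked genes. Sex was read from Xist and the Y-linked genes, since the labels do not give it. Gene coordinates are on mm10 and 1-based.

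Total reads ran from 1732783 to 19464892. A count of 0 allows up to 3 reads, which is 12.1 normalized counts in the shallowest library; these limits cover counting error only. The 32 pairs of libraries within a group differed by more than sampling noise (chi-square per degree of freedom 10.1 to 210), so none was counted as a duplicate. Replicate numbers did not pair libraries across groups, since 3 of 18 libraries were closest to a library with their own number. Reads near the 3' end may be shared between paralogs such as Bglap and Bglap2 or Mt1 and Mt2, and their values were not separated here. Data were simulated with these group sizes and depths, with independent genes and 1 spread per gene for all groups. The test then recovered 37.3% of 2-fold changes in either arthritis comparison, 28.4% between the control genotypes and 41.8% between the arthritic genotypes. Of 4-fold changes in WT arthritis, Sema3b-/- arthritis, control genotypes and arthritic genotypes it recovered 68.2%, 74.2%, 75.8% and 80.3%. In the real libraries the spread differed between groups. Chi-square per degree of freedom was 10.1 to 15.8 between WT control pairs and 34.6 to 210 between WT arthritis pairs. The simulated rates may therefore not hold for the real comparisons.

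Results were also computed with DESeq2 1.42.0, limma-voom, other normalization factors (RLE, and TMM with library sizes without muscle, epidermis and erythroid genes), no filter, a filter of CPM above 5 in at least 4 libraries, a fit of the 2 groups alone, the replicate number as a block, a fit without the 3 arthritis libraries whose titles have another form, a term for that form, a term for sex, a log2 fold change of at least 1 beside the adjusted p, and each library left out in turn. Added after the data were examined were edgeR 4.0.16 quasi-likelihood on recovered reads, alone and with a sex term, pseudocounts of 0.5 and 5, TMM factors, female libraries alone, male libraries alone, a sex term for the lists (also with an estimated correlation) and for the likeness of the arthritis effects, TMM factors for the lists, a fit with Sema3b left out of the genes tested, and fits without the 2 arthritis libraries with the least muscle and epidermis RNA or without the 2 Sema3b-/- controls with the most osteoblast RNA.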

Results

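Gene expression was measured in forepaws of C57BL/6 mice by CEL-seq, in which each RNA is read from a tag near its 3' end. Sema3b encodes a secreted class 3 semaphorin, a ligand of neuropilin and plexin receptors, and the mice were wild type (WT) or lacked the gene (Sema3b-/-). The 18 libraries fall into 4 groups: 4 WT control, 4 Sema3b-/- control, 5 WT arthritis and 5 Sema3b-/- arthritis. The labels do not name the arthritis model. The titles of all control libraries begin with one word and those of all arthritis libraries with others, so any difference in preparation that goes with the titles also goes with arthritis. Total reads per library ranged from 1732783 (Sema3b-/- control replicate 1) to 19464892 (WT arthritis replicate 2), an 11.2-fold range with a median of 7279063.5, and 13917 to 16572 of the 18585 genes had at least 1 read. By group, totals were 6086700 to 8179726 in WT control, 1732783 to 12816207 in Sema3b-/- control, 6251174 to 19464892 in WT arthritis and 5468160 to 10083213 in Sema3b-/- arthritis.

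The values of Sema3b followed the genotype in every library. Sema3b (mm10 chromosome 9, 107597674 to 107609229, minus strand, 19 exons in its principal transcript) was at 55.9 ± 10.8 normalized counts (SD, n = 4) in WT control and 44.4 ± 16.5 (SD, n = 5) in WT arthritis. It was at 2.95 ± 3.03 (SD, n = 4) in Sema3b-/- control and 1.29 ± 1.48 (SD, n = 5) in Sema3b-/- arthritis, from 0 to 6 reads per library. Sema3b-/- control replicate 1 and Sema3b-/- arthritis replicates 1 and 5 had 0 reads. There, 3 reads would be 12.1, 3.89 and 2.08 normalized counts, which is the level that a count of 0 allows. Which part of the gene the knockout removed is not given in the sources used here.

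The sex of the animals, read from Xist, the RNA that silences an X chromosome in females, and from 4 Y-linked genes, differed between the groups. All 4 WT control libraries were female, while 4 of the 5 WT arthritis libraries were male. Sema3b-/- control held 2 female and 2 male libraries, and Sema3b-/- arthritis 4 female and 1 male. Xist was at 351 ± 62.9 normalized counts (SD, n = 4) in WT control and at 2.55 to 9.60 in the 4 male WT arthritis libraries, where Ddx3y, a Y-linked RNA helicase, was at 757 to 1037. Over all genes, limma called none of the 5 sex-linked genes in WT arthritis against WT control. Adjusted over the list alone 4 rose and 1 fell. The comparison of WT arthritis with WT control is therefore also close to a comparison of males with females, and a fit with sex as a term is given beside it.

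The first comparison asks what arthritis changed in WT forepaws, with 5 arthritis and 4 control libraries. Il1b, which encodes the cytokine interleukin-1 beta, was at 432 ± 420 normalized counts (SD, n = 5) in arthritis and 21.5 ± 10.6 (SD, n = 4) in control, a log2 fold change of 3.37 (SE 0.88, limma adjusted p = 0.0436), a call that ended (adjusted p up to 0.121) without any 1 of 13 libraries, all but Sema3b-/- control replicates 3 and 4, WT arthritis replicates 1 and 2 and Sema3b-/- arthritis replicate 2. Ccl8, a chemokine that attracts monocytes, was at 2224 ± 1890.0 in arthritis and 192 ± 36.3 in control (log2 fold change 2.96, SE 0.63). Sox10, a transcription factor of Schwann cells, the glia of peripheral nerve, fell by 3.02 on the log2 scale (SE 0.64). With limma, 582 of 13809 genes tested passed an adjusted p of 0.05, 364 higher and 218 lower in arthritis, and 2934 had an unadjusted p under 0.05. The authors' deposited table called 481 genes, 349 higher and 132 lower. With sex as a term 133 genes passed (75 higher, 58 lower), of which 113 were among the 582, and all 582 kept their sign. The count fell to 188, 227, 149 and 263 without WT control replicates 1, 2, 3 and 4, and to 300, 189 and 285 without WT arthritis replicates 3, 4 and 5, and it was 1112 without WT arthritis replicate 2.

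Genes with no overlap between the WT groups included myeloid and early response genes. Fosb, a subunit of the AP-1 transcription factor, rose by 3.75 (SE 0.87, limma adjusted p = 0.0266) and Clec4d, a C-type lectin receptor of myeloid cells, by 3.38 (SE 0.65, adjusted p = 0.0116). Tnfaip6, a hyaluronan-binding protein induced in inflammation, rose by 2.88, Hp, the haemoglobin-binding acute phase protein haptoglobin, by 2.49, and Slpi, an inhibitor of neutrophil elastase, by 2.25. Atf3 and Nr4a1, stress-induced and early response transcription factors, rose by 2.32 and 2.23, and the interferon-induced ubiquitin-like protein Isg15 by 2.04. On the lower side Ltbp4, an extracellular matrix protein that binds latent TGF-beta, had the smallest adjusted p of these genes, with a log2 fold change of -1.93 (SE 0.22, adjusted p = 0.000439). Rapgefl1, a Rap guanine nucleotide exchange factor (-2.21), Nr1d1, a repressor of the circadian clock (-1.80), the laminin receptor Bcam (-1.60) and the hair cycle regulator Hr (-1.58) fell. So did Lars2, the mitochondrial leucyl-tRNA synthetase (-1.58), fatty acid synthase Fasn (-1.57) and Ppp1r13l, an inhibitor of p53 (-1.52). Of the 39 genes that the naming rule selected and limma called here, Atf3, Ccl9, Ccr2, Clec4d, Fasn, Lars2, Ltbp4, Lyz2, Nr1d1 and Ptx3 kept an adjusted p under 0.05 whichever library was left out, and the other 29 reached 0.0591 to 0.143. Lars2, Ltbp4, Nr1d1, Plxna1 and Sema4b stayed under 0.05 when sex was a term.

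**Figure D1:**
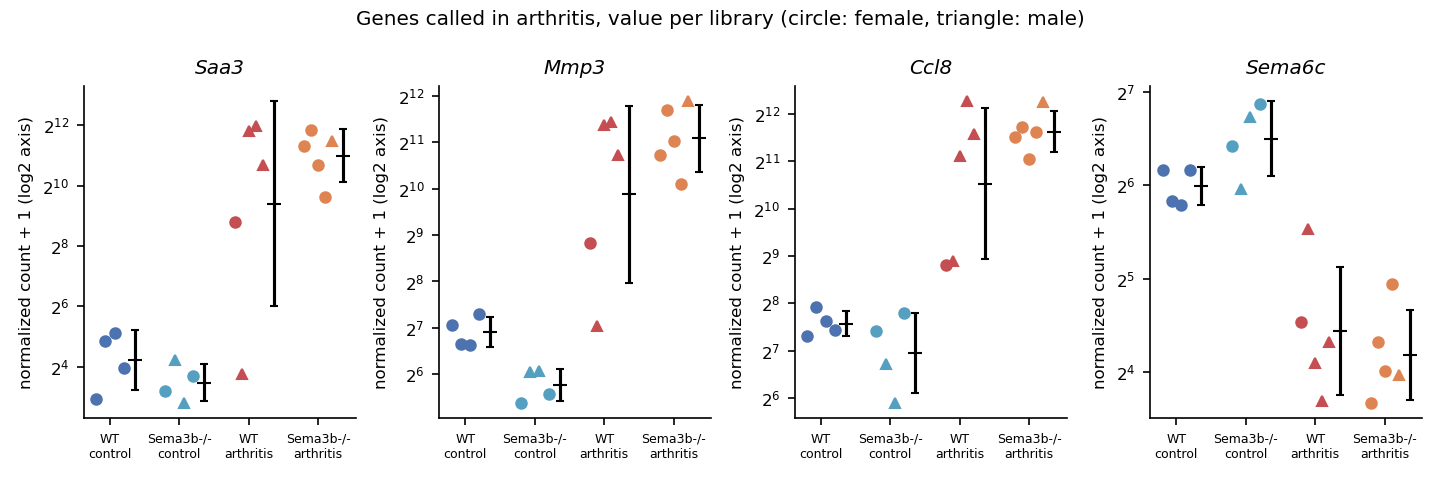
Normalized counts plus 1 of Saa3, Mmp3, Ccl8 and Sema6c in each of the 18 libraries on a log2 axis, by group; circles are female and triangles male libraries, and bars give the mean and SD of the log2 values. In WT arthritis replicate 2, Saa3 was at 12.6 and Mmp3 at 130, within the WT control ranges of 6.63 to 33.8 and 98.5 to 157.

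Myeloid and inflammatory lists moved up in WT arthritis. Of 14 monocyte and macrophage genes, 4 rose over all genes and 12 adjusted over the list alone, among them Lyz2, the lysozyme of myeloid cells, by 1.72 (SE 0.32), and Ccr2, the receptor of inflammatory monocytes, by 1.15 (SE 0.21); the median was 0.85 (camera adjusted p = 1.97e-08, adjusted p = 0.284 with an estimated correlation). Of 16 chemokines 3 rose, 9 adjusted over the list alone, with Cxcl5, a neutrophil attractant, at 4.02 (SE 1.06). The list median was 2.15 (adjusted p = 2.77e-05, adjusted p = 0.412 with an estimated correlation). Of 13 neutrophil genes Cxcr2, a chemokine receptor, rose by 1.57, and 6 rose adjusted over the list alone, with a median of 1.29 (adjusted p = 0.000219, adjusted p = 0.455 with an estimated correlation). Among 12 complement and acute phase genes 4 rose, 4 adjusted over the list alone: Saa3, serum amyloid A, by 5.19 (SE 1.27), Hp, the pentraxin Ptx3 by 2.03 and the protease inhibitor Serpina3n by 1.19. The median was 0.73 (adjusted p = 0.000305, adjusted p = 0.284 with an estimated correlation). Of 11 immediate early genes Atf3, Jun, Fosb and Nr4a1 rose, 5 adjusted over the list alone. Its median was 1.06 (adjusted p = 3.53e-06, adjusted p = 0.351 with an estimated correlation). Isg15 was the 1 of 14 interferon-stimulated genes that rose, 1 adjusted over the list alone. The list had a median of 0.69 (adjusted p = 0.00127, adjusted p = 0.455 with an estimated correlation). Mmp3, stromelysin, which degrades cartilage matrix, and Adamts1 rose by 2.96 and 1.21 among 14 proteases and inhibitors, 2 adjusted over the list alone (median 0.62, adjusted p = 0.00455, adjusted p = 0.455 with an estimated correlation).

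The same direction without called members was seen in cell cycle genes (0 of 14, 1 adjusted over the list alone; median 0.46, adjusted p = 0.00203, adjusted p = 0.464 with an estimated correlation) and in synovial fibroblast genes (0 of 14 and 0 adjusted over the list alone; median 0.47, adjusted p = 0.0283, adjusted p = 0.512 with an estimated correlation). The synovial fibroblast call ended without WT control replicate 2 or WT arthritis replicates 3 or 4, with an adjusted p of up to 0.208. Proinflammatory cytokines gave no call as a list (1 of 12 rose, 3 adjusted over the list alone, adjusted p = 0.133), although Il1b rose; Il6 was at 2.94 (SE 0.99, adjusted p = 0.0997). With sex as a term, camera no longer called the protease (adjusted p = 0.151), interferon (0.218) or synovial fibroblast list (0.56).

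Tissue and B cell lists moved down in WT arthritis. All 10 peripheral nerve genes had negative values, 2 fell over all genes and 7 adjusted over the list alone, with a median of -1.23 (camera adjusted p = 2.77e-05, adjusted p = 0.284 with an estimated correlation). Of 29 semaphorins and their receptors, Plxna1 (-0.89), Sema6c (-1.55, SE 0.34) and Sema4b (-1.26) were among the 4 that fell and Plxnc1, a plexin of leukocytes, rose by 1.3; adjusted over the list alone 1 rose and 6 fell. Its members had a median of -0.48 (adjusted p = 0.000824, adjusted p = 0.0597 with an estimated correlation). Bglap, the bone matrix protein osteocalcin, fell by 2.50 (SE 0.66) as the 1 call among 12 osteoblast and osteocyte genes, 2 adjusted over the list alone. The list median was -0.93 (adjusted p = 0.00203, adjusted p = 0.455 with an estimated correlation). None of 8 B cell genes (median -1.0, adjusted p = 0.00544, adjusted p = 0.455 with an estimated correlation), 11 epidermis genes (median -1.78, adjusted p = 0.00145, adjusted p = 0.464 with an estimated correlation) or 10 adipocyte genes (median -0.57, adjusted p = 0.0272, adjusted p = 0.512 with an estimated correlation) passed, over all genes or adjusted over the list alone. The 16 skeletal muscle genes were all negative, 0 over all genes and 1 adjusted over the list alone (median -0.83, adjusted p = 0.00244, adjusted p = 0.512 with an estimated correlation), and the call ended without WT arthritis replicate 3 (adjusted p = 0.166). The adipocyte call ended without WT control replicate 4 or WT arthritis replicates 1 or 3 (adjusted p up to 0.185). Neither the muscle (0.151) nor the adipocyte list (0.124) was called by camera with sex as a term. Osteoclasts, cartilage, oxidative phosphorylation, erythroid cells, T and NK cells and endothelium gave no camera call (adjusted p 0.293, 0.311, 0.133, 0.613, 0.976 and 0.501) and no called member. Osteoclasts (camera adjusted p = 0.00211) and endothelium (0.0075) were called lower with sex as a term, but not with an estimated correlation (adjusted p = 0.432 for both).

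Muscle and skin made up different shares of the RNA within WT arthritis. The muscle list took 2.05 ± 1.5% of normalized counts in WT arthritis (SD, n = 5) and 3.16 ± 0.318% in WT control (SD, n = 4, exact permutation p = 0.175, two-sided), and the epidermis list 0.868 ± 0.924% and 2.13 ± 0.374% (exact permutation p = 0.0476, adjusted over 24 such tests 0.286). WT arthritis replicate 3 held the least of both, 0.263% and 0.0578%. Mitochondrial transcripts made up 39.4% in WT arthritis replicate 1 and 20.3 ± 0.550% in WT control.

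The second comparison asks the same of Sema3b-/- forepaws, with 5 arthritis and 4 control libraries. Saa3 was at 2307 ± 1129 normalized counts (SD, n = 5) in arthritis and 11 ± 5.24 (SD, n = 4) in control, a log2 fold change of 7.51 (SE 1.27, limma adjusted p = 0.0028). Mmp3 was at 2402 ± 1124 and 54.6 ± 13.0 (log2 fold change 5.33, SE 0.72), and the neutrophil attractants Cxcl5 and Cxcl1 rose by 6.31 (SE 1.06) and 5.56 (SE 1.08). Chad, chondroadherin, was at -2.59 (SE 0.54) and Cilp2, a cartilage matrix protein, at -2.73 (SE 0.34). With limma 1710 of 13809 genes passed, 944 higher and 766 lower in arthritis, and 3941 had an unadjusted p under 0.05. The authors' deposited table called 973, 538 higher and 435 lower. The count was 995 without Sema3b-/- control replicate 3 and 975 and 1083 without Sema3b-/- arthritis replicates 2 and 5, and 1839 with sex as a term.

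Other genes that the naming rule took for their changes in Sema3b-/- arthritis, in groups without overlap, were Il1b (5.01), the monocyte attractants Ccl7 (4.81), Ccl8 (4.67) and Ccl2 (4.12), Tnfaip6 (4.05) and Clec4e (3.87), a receptor for damaged cells and mycobacterial glycolipid, all of which rose. On the lower side Lars2 had the smallest adjusted p of all named genes, with a log2 fold change of -2.45 (SE 0.22, limma adjusted p = 2.94e-05). Npy, a neuropeptide (-2.59), Clec3a, a cartilage lectin (-2.47), and Nccrp1, which is found in stratified epithelia (-2.76), fell. The muscle genes Csrp3, a protein of the Z-disc, and Slc2a4, the insulin-responsive glucose transporter, had values of -2.49 and -2.35, and the membrane proteins Yipf7 and Tmem52 of -2.59 and -2.46. Of the 54 genes that the naming rule selected and limma called here, 33 kept an adjusted p under 0.05 whichever library was left out. The highest adjusted p of the other 21, among them Csrp3, Yipf7, Nccrp1, Tmem52 and Slc2a4, was 0.0515 to 0.134. Members of the lists given below were also among these 21. The Has1 call ended without any 1 of 16 libraries, Ndufs1 and Vwf of 12 each, Il6 of 8, Col2a1 of 7 and Osm of 6. Col2a1 (0.062) and Vwf (0.0507) were no longer under 0.05 when sex was a term.

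Myeloid and inflammatory lists moved up in Sema3b-/- arthritis. Of 16 chemokines 13 rose, 13 adjusted over the list alone, with Cxcl13, which attracts B cells, at 5.11 (SE 0.76). Across the list the median was 3.54 (camera adjusted p = 5.12e-12, adjusted p = 0.182 with an estimated correlation). Of 14 monocyte and macrophage genes 11 rose, 12 adjusted over the list alone, with Ccr2 at 2.10 (SE 0.21) and Mrc1, the mannose receptor, at 1.20. The median was 1.35 (adjusted p = 8.34e-12, adjusted p = 0.182 with an estimated correlation). Of 12 complement and acute phase genes 7 rose, 8 adjusted over the list alone, with Ptx3 at 3.11 (SE 0.43) and Serpina3n at 2.06. Across the list the median was 1.39 (adjusted p = 9.2e-07, adjusted p = 0.182 with an estimated correlation). Of 14 interferon-stimulated genes 7 rose, 13 adjusted over the list alone, with Isg15 at 2.00. The median was 1.72 (adjusted p = 8.98e-08, adjusted p = 0.21 with an estimated correlation). Of 12 proinflammatory cytokines 5 rose, 6 adjusted over the list alone, with Il6 at 3.29 (SE 0.99) and Osm, oncostatin M, at 2.46. Its median was 1.33 (adjusted p = 0.00117, adjusted p = 0.182 with an estimated correlation). Mmp3, Adamts1 and Timp1, an inhibitor of matrix proteases, were among 4 of 14 protease genes that rose, 5 adjusted over the list alone (median 0.78, adjusted p = 0.00775, adjusted p = 0.373 with an estimated correlation, adjusted p = 0.104 without Sema3b-/- control replicate 4).

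Smaller shifts upward were seen in stromal, cycling and early response genes of Sema3b-/- forepaws. Pdpn, the podoplanin of lining fibroblasts, rose by 2.56 (SE 0.42) and Has1, a hyaluronan synthase, by 1.26, among 3 of 14 synovial fibroblast genes, 3 adjusted over the list alone. The list had a median of 0.37 (camera adjusted p = 0.0284, adjusted p = 0.495 with an estimated correlation). Pcna, the sliding clamp of DNA replication, rose by 0.57 as the 1 of 14 cell cycle genes, 1 adjusted over the list alone. Its members had a median of 0.35 (adjusted p = 0.0166, adjusted p = 0.495 with an estimated correlation). Of 11 immediate early genes 0 passed and 4 adjusted over the list alone. The list median was 0.70 (adjusted p = 0.0284, adjusted p = 0.495 with an estimated correlation). These 3 list calls ended when 1 library was left out: Sema3b-/- control replicate 4 or Sema3b-/- arthritis replicates 2 or 5 for synovial fibroblasts (adjusted p up to 0.297), Sema3b-/- control replicates 3 or 4 or Sema3b-/- arthritis replicate 2 for cell cycle (up to 0.0967), and Sema3b-/- control replicates 2 or 3 or Sema3b-/- arthritis replicates 3 or 4 for immediate early genes (up to 0.202, and 0.0649 with sex as a term). Neutrophil genes gave no list call (2 of 13 rose, 2 adjusted over the list alone, adjusted p = 0.104), but were called higher with sex as a term (0.049, adjusted p = 0.546 with an estimated correlation).

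Bone, cartilage, B cell and tissue lists moved down in Sema3b-/- arthritis. Of 12 osteoblast and osteocyte genes 5 fell, 10 adjusted over the list alone, with Bglap at -3.60 (SE 0.66) and Alpl, the alkaline phosphatase of mineralizing bone, at -1.81. Across the list the median was -1.54 (camera adjusted p = 1.48e-05, adjusted p = 0.246 with an estimated correlation). Of 11 cartilage genes 3 fell, 4 adjusted over the list alone, with Col2a1, the main cartilage collagen, at -3.05 (SE 0.90) and Chad. The median was -1.42 (adjusted p = 0.00776, adjusted p = 0.373 with an estimated correlation). Of 10 peripheral nerve genes 5 fell and 1 rose, 6 and 1 adjusted over the list alone, with Prx, periaxin of myelinating Schwann cells, at -1.85 and Mbp, myelin basic protein, at -1.20. Its median was -0.91 (adjusted p = 0.00546, adjusted p = 0.373 with an estimated correlation). Of 8 B cell genes 2 fell, 7 adjusted over the list alone, with Cd79a, a signalling chain of the B cell receptor, at -2.18. The list had a median of -1.99 (adjusted p = 0.000141, adjusted p = 0.246 with an estimated correlation). Sema6c (-2.32, SE 0.34) and Sema4b (-1.26) were among 5 semaphorins and receptors that fell, and 1 rose; adjusted over the list alone 3 rose and 7 fell (median -0.36, adjusted p = 0.0284, adjusted p = 0.185 with an estimated correlation), and the call ended without Sema3b-/- control replicates 2 or 3 (adjusted p up to 0.113). Of 20 oxidative phosphorylation genes 4 fell, 10 adjusted over the list alone, among them the complex I subunits Ndufv1 (-0.76) and Ndufs1 (-0.66), and all 20 were negative. Its members had a median of -0.42 (adjusted p = 2.76e-05, adjusted p = 0.379 with an estimated correlation). Lep, leptin, fell by 1.97 among 10 adipocyte genes, 2 adjusted over the list alone (median -0.90, adjusted p = 0.00117, adjusted p = 0.373 with an estimated correlation).

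No member of the muscle, epidermis or erythroid lists passed in Sema3b-/- arthritis, over all genes or adjusted over the list alone, while camera placed each list lower. Medians were -1.71 over 16 muscle genes (camera adjusted p = 3.09e-05, adjusted p = 0.381 with an estimated correlation), -1.35 over 11 epidermis genes (adjusted p = 0.0205, adjusted p = 0.502 with an estimated correlation) and -1.96 over 6 erythroid genes (adjusted p = 0.0205, adjusted p = 0.459 with an estimated correlation). The epidermis call ended without Sema3b-/- control replicate 4 or Sema3b-/- arthritis replicate 2 (adjusted p up to 0.202), and the erythroid call without Sema3b-/- control replicate 2 or Sema3b-/- arthritis replicates 3 or 5 (up to 0.0887). Muscle genes made up 1.40 ± 0.765% of normalized counts in arthritis (SD, n = 5) and 3.79 ± 1.3% in control (SD, n = 4, exact permutation p = 0.00794, two-sided, the smallest this design allows, adjusted over 24 tests 0.19). Osteoblast genes made up 0.562 ± 0.268% and 2.51 ± 2.17% (exact permutation p = 0.0476, adjusted over 24 tests 0.286), with 4.15% and 4.59% in Sema3b-/- control replicates 2 and 3, the male libraries of that group, and without those replicates 1045 genes passed. Endothelium, osteoclasts and T and NK cells gave no camera call (adjusted p 0.0726, 0.602 and 0.987); Vwf, a clotting factor carrier, was 1 of 2 endothelial genes that fell (-0.75), 2 adjusted over the list alone.

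**Figure D2:**
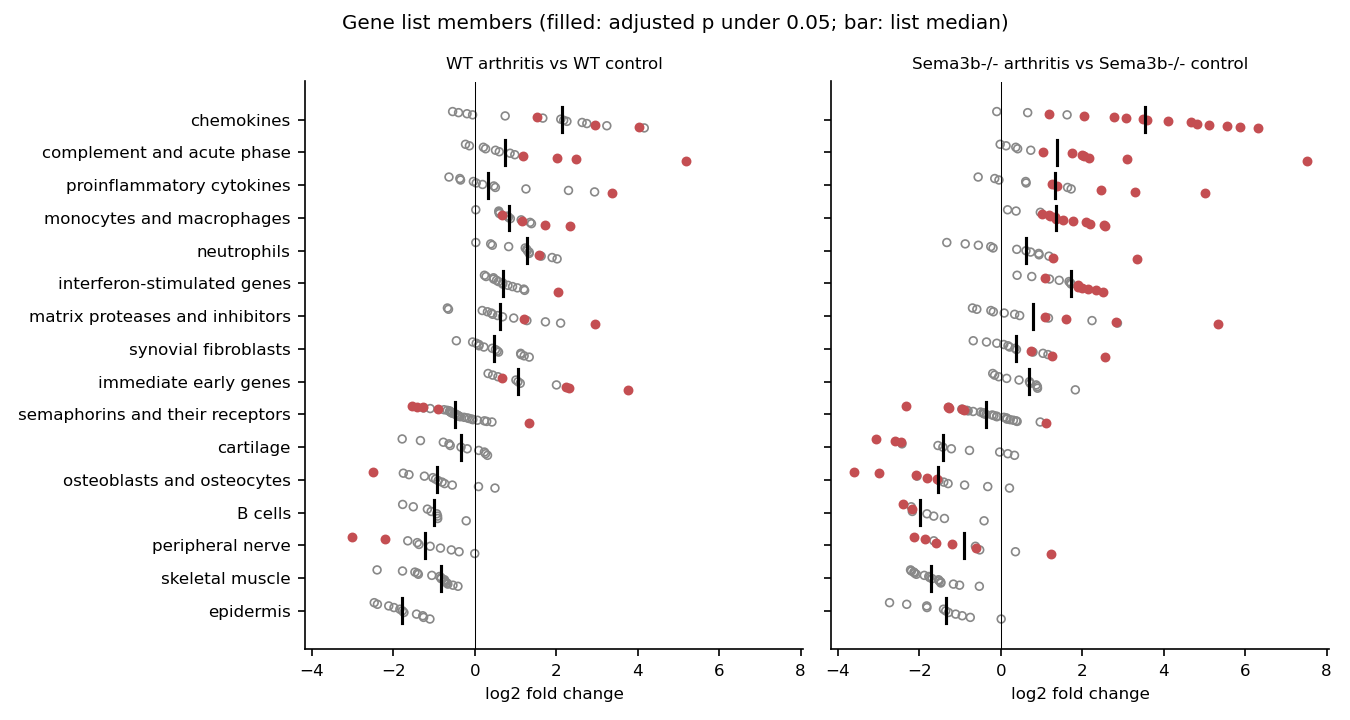
Log2 fold change of each member of 16 gene lists in the arthritis comparison of WT (5 against 4 libraries) and of Sema3b-/- (5 against 4); filled points have a limma adjusted p under 0.05 and the bar is the median of the list. The chemokine medians were 2.15 in WT and 3.54 in Sema3b-/-.

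How alike the responses of the genotypes were was asked across genes, which are not independent replicates, with no library shared between the 2 comparisons. Both came from the same fit, so they share the estimate of spread of each gene. Calls can therefore coincide more often than the numbers given as chance, which take calls as independent. With sex as a term they also share the sex effect of each gene. The share of males rises in WT and falls in Sema3b-/-, so an error in that effect enters with opposite signs and can lower the likeness. Genes higher in arthritis in both genotypes numbered 248, against 24.9 by chance, and included Il1b, Ccl8, Saa3 and Mmp3; 134 were lower in both, against 12.1, and included Ltbp4 and Lars2. None was called in opposite directions. Log2 fold changes had a Pearson correlation of 0.644 and a Spearman correlation of 0.652 over 13809 genes. Of the 582 genes called in WT 569 had the same sign in Sema3b-/-, and of the 1710 called in Sema3b-/- 1623 had the same sign in WT. The median ratio of Sema3b-/- to WT change was 0.859 over the WT calls, and that of WT to Sema3b-/- change 0.581 over the Sema3b-/- calls. Each ratio divides by the change for which its genes were picked. Picking alone can lower both, so they do not measure which genotype responded more. With sex as a term 49 genes were higher and 32 lower in both, against 5.72 and 3.30 by chance, the ratios were 0.632 and 0.414 and the Pearson correlation 0.432, and Il1b, Ccl8, Saa3 and Mmp3 were not called in WT (adjusted p 0.263, 0.134, 0.18 and 0.246). Their WT log2 fold changes were then 2.68 (SE 1.09), 2.64 (SE 0.80), 4.83 (SE 1.64) and 2.22 (SE 0.87), each lower and with a larger error than 3.37 (SE 0.88), 2.96 (SE 0.63), 5.19 (SE 1.27) and 2.96 (SE 0.72) without that term. Without the 3 arthritis libraries whose titles have another form 47 were higher and 40 lower in both, with a correlation of 0.478, and by DESeq2 492 and 236.

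**Figure D3:**
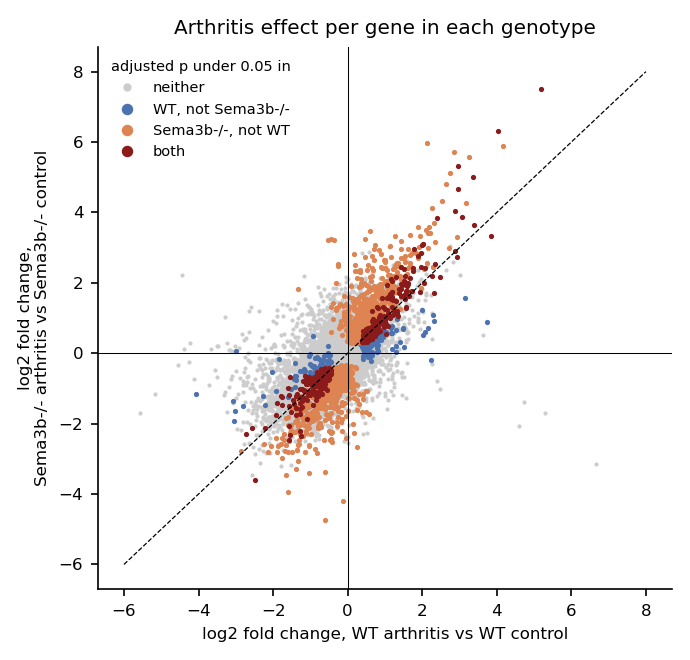
Log2 fold change with arthritis in Sema3b-/- (vertical axis) against that in WT (horizontal axis) for 13809 genes; colours mark genes called by limma in both genotypes, in 1 of them or in neither, and the dashed line is equality. The 248 genes called higher and 134 called lower in both lie in the upper right and lower left, and none lies in the other corners.

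The genotypes were compared in control forepaws, with 4 libraries each, to ask what loss of Sema3b changed without arthritis. Sema3b itself was lower in Sema3b-/-, with a log2 fold change of -4.19 (SE 0.60, limma adjusted p = 0.0234), a fitted value that was -4.57 (adjusted p = 0.0917) with an added count of 0.5 in place of 1 and -2.99 with 5. Gas5 (chromosome 1, 161034601 to 161038539), a noncoding RNA that hosts small nucleolar RNAs, was at 541 ± 37.6 normalized counts (SD, n = 4) in Sema3b-/- and 983 ± 52.0 (SD, n = 4) in WT, and fell by 0.86 (SE 0.14, limma adjusted p = 0.0385). These 2 genes, both lower, were the limma calls, and 811 genes had an unadjusted p under 0.05; DESeq2 called 5, voom 0 and the authors' deposited results 0. The next lowest p values belonged to Usp40, a ubiquitin protease (-1.17, SE 0.21), Lpar6, a receptor of lysophosphatidic acid (-0.86, SE 0.16), and Eomes, a transcription factor of NK and T cells (-3.20, SE 0.60), with adjusted p of 0.121 to 0.125. With sex as a term 0 genes passed (882 at an unadjusted p under 0.05), with Sema3b at -4.20 (adjusted p = 0.121) and Gas5 at -0.85 (adjusted p = 0.22). With Sema3b, the gene the design alters, left out of the genes tested, limma called 0 genes (810.0 at an unadjusted p under 0.05) and Gas5 had an adjusted p of 0.0769. Leaving out any 1 of 13 libraries ended the Gas5 call, with an adjusted p of 0.0576 to 0.261, and any 1 of 9 ended that of Sema3b, 0.0507 to 0.185. No gene passed without any 1 of the WT control replicates, Sema3b-/- control replicates 1, 2 or 3, or WT arthritis replicates 4 or 5, and 1 without Sema3b-/- control replicate 4, WT arthritis replicates 1 or 3 or Sema3b-/- arthritis replicate 5.

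**Figure D4:**
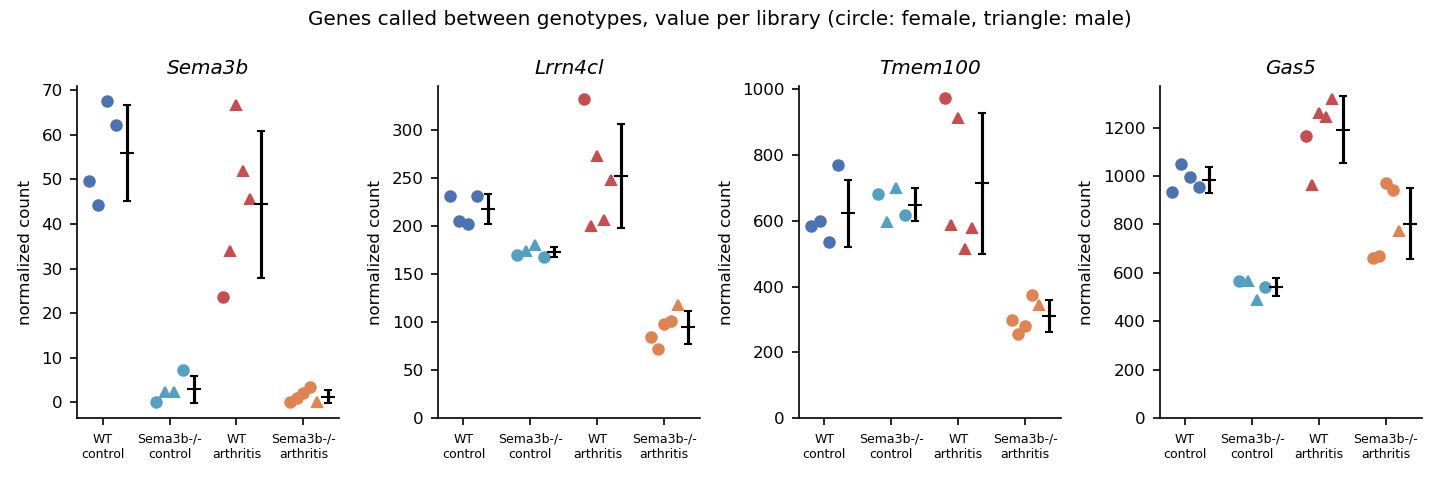
Normalized counts of Sema3b, Lrrn4cl, Tmem100 and Gas5 in each of the 18 libraries on linear axes, by group, with the mean and SD as bars; circles are female and triangles male libraries. Lrrn4cl was at 72 to 117 in the 5 Sema3b-/- arthritis libraries and at 199.8 to 333 in the 5 WT arthritis libraries.

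Camera at its preset correlation of 0.01 called gene lists between genotypes in control forepaws, in members that did not pass as single genes. Cell cycle genes were higher in Sema3b-/- (median 0.54, camera adjusted p = 5.38e-07), as were neutrophil (0.82, adjusted p = 0.00655), oxidative phosphorylation (0.19, adjusted p = 0.00655), erythroid (1.35, adjusted p = 0.0103) and osteoclast genes (0.33, adjusted p = 0.0257). Adipocyte genes (-0.61, adjusted p = 0.00109), chemokines (-0.55, adjusted p = 0.00655) and complement genes (-0.60, adjusted p = 0.0103) were lower. With an estimated correlation each of these 8 lists had an adjusted p = 0.922. In these 8 lists no gene passed over all genes or adjusted over the list alone, and 3 lists were called without Sema3b-/- control replicates 2 and 3. Among the 8, the cell cycle call held whichever library was left out. Each of the others ended without at least 1 library. It was Sema3b-/- control replicate 3 for chemokines, complement and adipocytes (adjusted p = 0.0819, 0.139 and 0.0558), Sema3b-/- control replicate 2 for neutrophils (0.254, and 0.107 with sex as a term) and Sema3b-/- control replicate 4 for oxidative phosphorylation (0.952). It was WT control replicate 4 or Sema3b-/- control replicate 2 for erythroid genes (up to 0.166), and WT control replicates 2 or 4 or Sema3b-/- control replicates 2 or 3 for osteoclasts (up to 0.606, and 0.7 with sex as a term). Interferon-stimulated genes (camera adjusted p = 0.00402) and monocyte and macrophage genes (0.0477) were called lower in Sema3b-/- control with sex as a term, but not with an estimated correlation (adjusted p = 0.735 and 0.821).

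In arthritic forepaws the genotypes were compared over 5 libraries each, the contrast closest to the question of what Sema3b does in arthritis. Sema3b-/- arthritis held 4 female libraries and 1 male, and WT arthritis 1 female and 4 male, so genotype here largely goes with sex. Lrrn4cl (chromosome 19, 8850768 to 8853909), a small membrane protein, was at 94.6 ± 17.3 normalized counts (SD, n = 5) in Sema3b-/- and 252 ± 54.1 (SD, n = 5) in WT, and fell by 1.40 (SE 0.15, limma adjusted p = 0.000385). Tmem100 (chromosome 11, 90030348 to 90036508), a membrane protein induced by BMP signalling in endothelium, was at 310 ± 48.0 and 713 ± 213 and fell by 1.16 (SE 0.17, limma adjusted p = 0.0106). Sema3b fell by 4.48 (SE 0.54, limma adjusted p = 0.000986), a fitted value that was -5.03 with an added count of 0.5 and -2.93 with 5. These 3 genes, all lower, were the limma calls and 1239 had an unadjusted p under 0.05, while the authors' deposited table called 2, both lower. DESeq2 called 94 genes (20 higher, 74 lower), which included the 3. Abhd14b, a hydrolase encoded near Sema3b, was at 63.7 ± 29.8 and 236 ± 83.3 (-1.91, SE 0.33, adjusted p = 0.0614), and Dnajb4, a co-chaperone, at 103 ± 22.1 and 186 ± 19.1 (-0.87, SE 0.15, adjusted p = 0.0614).

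Lrrn4cl, Tmem100 and Sema3b stayed among 4 calls in the arthritic genotype comparison when sex was a term. A fit of female libraries alone has a single WT arthritis library, replicate 1, assumed to vary like the others. Mitochondrial transcripts made up 39.4% of that library, against 15.7 to 27.9% in the other arthritis libraries. In that fit Lrrn4cl was at -1.90 and Tmem100 at -1.70. Among male libraries, with 1 Sema3b-/- arthritis library, they were at -0.963 and -0.879. Tmem100 had an adjusted p of 0.0517 without Sema3b-/- arthritis replicate 2, 0.0858 with the replicate block, 0.0943 without the 2 arthritis libraries with the least muscle and epidermis RNA and 0.325 with the 2 groups alone, where that of Lrrn4cl was 0.0537. Without the 3 arthritis libraries whose titles have another form 0 genes passed, with Lrrn4cl at -1.22 (adjusted p = 0.0528), Sema3b at -4.14 (0.0581) and Tmem100 at -1.12 (0.234). The count was 5 without WT arthritis replicate 2 or Sema3b-/- arthritis replicates 3, 4 or 5, 6 without WT arthritis replicate 4 and 2 without Sema3b-/- arthritis replicate 2.

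Inflammatory and tissue lists also separated the genotypes in arthritis by camera, without any called member besides Sema3b. Higher in Sema3b-/- were cell cycle genes (median 0.45, camera adjusted p = 3.53e-06), chemokines (0.98, adjusted p = 0.000183, 1 of 16 adjusted over the list alone), monocyte and macrophage genes (0.36, adjusted p = 0.00109, 1 of 14), proinflammatory cytokines (0.76, adjusted p = 0.00305, 2 of 12), interferon-stimulated genes (0.55, adjusted p = 0.00305, 0 of 14) and osteoclast genes (0.42, adjusted p = 0.0032, 0 of 11). Lower were adipocyte genes (-1.07, adjusted p = 2.23e-08, 7 of 10 adjusted over the list alone), immediate early genes (-0.50, adjusted p = 0.00305, 2 of 11), cartilage (-0.71, adjusted p = 0.00452, 0 of 11) and B cell genes (-0.66, adjusted p = 0.00452, 1 of 8). With an estimated correlation the adjusted p was 0.44 for cytokines and adipocytes and 0.543 for the other 8. In WT arthritis replicate 2, Saa3 (12.6 normalized counts) and Mmp3 (130) lay within the WT control ranges. It was at -40.1 on the first principal component, where WT control was at -45.7 to -37.7. This library of WT arthritis resembled control in these values, but not in all. Neutrophil genes made up 0.830% of its RNA, against 0.110 to 0.188% in WT control. Mitochondrial transcripts made up 27.9%, against 19.9 to 21.1%. The calls of cell cycle, chemokines, cytokines and adipocytes held whichever library was left out, and without that replicate the adjusted p was 0.0364 for chemokines and 0.0324 for cytokines. The others ended without WT arthritis replicate 2 (monocytes and macrophages 0.0978, interferon up to 0.116), Sema3b-/- arthritis replicate 5 (interferon), Sema3b-/- arthritis replicate 2 (osteoclasts 0.0669), WT arthritis replicate 3 (cartilage 0.107), Sema3b-/- arthritis replicate 3 (B cells 0.122), or WT arthritis replicate 3 or Sema3b-/- arthritis replicate 1 (immediate early genes, up to 0.124), and with sex as a term cartilage and B cells were not called (adjusted p = 0.144 and 0.142). In that fit oxidative phosphorylation (camera adjusted p = 0.00103) and skeletal muscle genes (0.0174) were called lower in Sema3b-/- arthritis, but not with an estimated correlation (adjusted p = 0.748 and 0.762).

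The 15 genes next to Sema3b that were tested, of 19 listed, on chromosome 9 were not called between genotypes by limma over all genes in either condition. Adjusted over the list alone, 1 was higher in Sema3b-/- control, Hyal1 (adjusted p = 0.0246). This hyaluronidase gene, which lies near Sema3b, had log2 fold changes of 1.16 (SE 0.31, adjusted p = 0.793) in control and 0.82 (SE 0.28, adjusted p = 0.397) in arthritis. With arthritis, Nat6 fell by 0.72 in WT (SE 0.19, adjusted p = 0.0452) and Tmem115 by 0.57 in Sema3b-/- (SE 0.14, adjusted p = 0.0174); the Nat6 call ended without any 1 of 11 libraries (adjusted p up to 0.143) and that of Tmem115 without Sema3b-/- control replicate 1 (0.0551). Across genes, the genotype effects in control and in arthritis had a Pearson correlation of 0.0795 and a Spearman correlation of 0.117.

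Whether arthritis acted differently in the genotypes was tested as an interaction in the same limma fit. The lowest p values belonged to Per1, a core gene of the circadian clock, which was at 81.0 ± 18.1 normalized counts in WT control, 120 ± 15.3 in WT arthritis, 187 ± 61.6 in Sema3b-/- control and 58.8 ± 31.9 in Sema3b-/- arthritis (interaction -2.32, SE 0.45), and to Lpar6 (1.03, SE 0.21), Errfi1, an inhibitor of EGF receptor signalling (-1.33, SE 0.28), Tmem100 (-1.23, SE 0.26) and Lrrn4cl (-1.07, SE 0.23). All 5 had an adjusted p of 0.449, and limma called 0 genes, with 663 at an unadjusted p under 0.05. By edgeR and voom 0 genes passed and by DESeq2 6 (1 higher, 5 lower); in female libraries alone, with a single WT arthritis library assumed to vary like the others, limma called 6. The larger number of calls in Sema3b-/- than in WT arthritis is therefore not shown to be a difference between genotypes.

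The authors also deposited the 2 comparisons that change genotype and treatment together. Sema3b-/- arthritis against WT control gave 1491 limma calls, 887 higher and 604 lower in Sema3b-/- arthritis, and the deposited results held 1012, 636 higher and 376 lower. WT arthritis against Sema3b-/- control gave 1253, 709 higher and 544 lower in WT arthritis, and the deposited results held 738, 420 higher and 318 lower. The first count was 915, 892, 786 and 766 without WT control replicates 1, 2, 3 and 4 and 834 without Sema3b-/- arthritis replicate 2. The second was 617 without Sema3b-/- control replicate 3 and 766, 619 and 823 without WT arthritis replicates 3, 4 and 5.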

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

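The test of genes around Sema3b was chosen only after its result was seen, and those of glucocorticoid-responsive and clock genes only after the values of Per1 and Tsc22d3 were seen; the splits without Sema3b were added after the other splits.

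Camera at its preset correlation of 0.01 called 13 gene lists in the interaction, whose values are differences between 2 arthritis effects and not levels. They were positive for chemokines (median 1.72, camera adjusted p = 2.16e-07), interferon-stimulated genes (0.58, adjusted p = 0.000687), monocyte and macrophage genes (0.40, adjusted p = 0.000869), complement and acute phase genes (0.56, adjusted p = 0.00411) and cytokines (0.45, adjusted p = 0.0113). They were negative for oxidative phosphorylation (-0.30, adjusted p = 0.000414), immediate early (-0.48, adjusted p = 0.00602), osteoblast (-0.60, adjusted p = 0.0151), cartilage (-1.03, adjusted p = 0.0206), erythroid (-1.50, adjusted p = 0.0236), neutrophil (-0.94, adjusted p = 0.0286), muscle (-0.68, adjusted p = 0.0475) and B cell genes (-0.64, adjusted p = 0.0475). With an estimated correlation the adjusted p was 0.734 for muscle and 0.627 to 0.637 for the others, so none was called. In the fit with sex as a term, the estimated correlations ran from 0.131 (cytokines) to 0.897 (muscle), above the preset 0.01. Some of these values go with control levels: by camera, in Sema3b-/- control chemokines (-0.55) and complement (-0.60) were lower and neutrophil (0.82), erythroid (1.35) and oxidative phosphorylation genes (0.19) higher, while between arthritic genotypes complement (0.14), neutrophil (-0.07), erythroid (-0.06) and oxidative phosphorylation genes (-0.12) were not called (camera adjusted p = 0.266, 0.994, 0.803 and 0.0573) and chemokines were higher (0.98, adjusted p = 0.000183, 0.543 with an estimated correlation). With an estimated correlation the 5 control differences had an adjusted p of 0.922, and each call ended without 1 Sema3b-/- control library: replicate 3 for chemokines (0.0819) and complement (0.139), replicate 2 for neutrophils (0.254) and erythroid genes (up to 0.166, also without WT control replicate 4) and replicate 4 for oxidative phosphorylation (0.952). Chemokines, monocytes and macrophages, complement and interferon held whichever library was left out. Without the library that weighed most, adjusted p was 0.0735 for oxidative phosphorylation (Sema3b-/- control replicate 4), 0.0878 for cytokines (Sema3b-/- control replicate 3) and up to 0.0975 for immediate early genes (Sema3b-/- control replicate 4 or WT arthritis replicate 3). It was up to 0.266 for osteoblasts (Sema3b-/- control replicates 2 and 3, WT arthritis replicate 3, Sema3b-/- arthritis replicate 3), and for neutrophils, cartilage, muscle, erythroid and B cells 7 to 10 libraries each ended the call (up to 0.342, 0.156, 0.66, 0.189 and 0.352). With sex as a term the osteoblast list turned to the opposite direction (adjusted p = 0.767), and neutrophils (0.767), cytokines (0.0615), cartilage (0.525), erythroid (0.052) and B cells (0.715) were not called, while osteoclasts (0.0036) and synovial fibroblasts (0.0403) had positive calls, but not with an estimated correlation (0.615 and 0.696). No single gene passed (limma 0, with 663 at an unadjusted p under 0.05; edgeR 0, voom 0, DESeq2 6).

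Single libraries lay far from the rest of their group in 13 of 220 groups of values, where chance gives about 1 in 20 groups. The numbers in parentheses are the gap to the nearest library as a share of the range. In WT control, replicate 1 had 0.758% erythroid RNA against 0.299 to 0.349% in the others (0.892), replicate 2 had 21.1% mitochondrial RNA against 19.9 to 20% (0.885), replicate 4 had Bcam at 539.7 against 439 to 452 (0.871), and replicate 3 had Tmem52 at 132 against 206 to 221 (0.834). In Sema3b-/- control, replicate 1 had Fosb at 12.1 against 38 to 43.2 (0.833), which is 3 reads in this shallowest library. Replicate 2 of that group had Hp at 731 against 239.8 to 303 (0.871) and Bcam at 250.3 against 522 to 567 (0.859). In WT arthritis, replicate 2 had Ppp1r13l at 172 against 82.8 to 98.9 (0.819) and Slc2a4 at 266 against 42.5 to 101 (0.737), replicate 3 had Cxcl1 at 788 against 5.23 to 209 (0.739), replicate 1 had Clec3a at 633 against 35.7 to 186 (0.748), and replicate 4 had Eomes at 12.8 against 3.17 to 5.23 (0.785). In Sema3b-/- arthritis replicate 4, Ccl7 was at 3946 against 1788 to 2350.4 (0.739).

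In the comparisons with arthritis on 1 side, few splits of the same libraries, the real one included, called as many genes as the real one. These shares bear on the total count and were not adjusted for the number of comparisons. They do not exclude chance for single calls. For WT arthritis, 3 of 100 splits called as many genes (582 in the real one; highest other 1044, in a split that put WT arthritis replicate 2 with controls); for Sema3b-/- arthritis 1 of 100 (1710; 642), for WT control against Sema3b-/- arthritis 1 of 100 (1491; 618), and for Sema3b-/- control against WT arthritis 2 of 100 (1253; 1612). Between genotypes 1 of 35 splits in control (2; 0) and 4 of 100 in arthritis (3; 966) called as many, but Sema3b itself separates the real split by design. With Sema3b left out of the genes tested, the control comparison had 0 limma calls (0 in the others too), so its 35 of 35 splits say nothing about chance. The arthritis comparison then had 2 calls, and 6 of 100 splits called as many (highest other 966), so chance was not excluded for that count. The splits count genes of any kind and say nothing about Lrrn4cl or Tmem100 singly; leaving out 1 library never ended the limma call of Lrrn4cl (adjusted p up to 0.00264), and that of Tmem100 ended without Sema3b-/- arthritis replicate 2 (0.0517). In arthritis the split that called 966 genes points to a structure of the samples other than genotype: it set WT arthritis replicates 1 and 2 with Sema3b-/- arthritis replicates 1, 3 and 4. This part was at -40.1 to 9.54 on the first principal component (38.1% of the variance) and the other at 12.2 to 123, with 1.55 to 3.98% against 0.263 to 1.6% of skeletal muscle RNA and 1 male library against 4, and which of these underlies the split was not tested. For the interaction the real count was 0 (limma; highest other 0), so that 100 of 100 regroupings had as many says nothing about chance.

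The 582 genes called in WT arthritis coincide with a change from female to male libraries. Sex as the whole cause was argued against by the Sema3b-/- comparison, where the share of males falls: 0.978 of the called genes outside the sex-linked ones had the same sign there. A response to arthritis is the biological explanation the design gives, and the median gene kept 0.954 of its fold change with sex as a term, while the count fell to 133. A difference in preparation between control and arthritis libraries cannot be told apart from arthritis, since the form of the title separates them fully. Sex may still have shaped single genes, since 1 WT arthritis library was female and no WT control library was male.

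Genes around Sema3b differed between genotypes in both conditions more often than genes elsewhere. Within 5 Mb of the gene, 8 of 134 genes had an unadjusted p under 0.05 and the same sign in control and arthritis, against 84 of 12966 on other chromosomes and 5 of 643 on the rest of chromosome 9. The values in control and arthritis were -1.33 and -1.91 for Abhd14b, -0.60 and -0.67 for Abhd14a, -0.46 and -0.37 for Tcta, 0.54 and 0.39 for Pik3r4, 0.76 and 0.95 for Hemk1, 0.49 and 0.38 for Tusc2, 0.50 and 0.46 for Nudt16 and 1.16 and 0.82 for Hyal1, and limma called none of them. A chromosome segment carried along with the targeted locus may be the cause (Fisher exact p = 4.62e-06 against all other genes). The share was also higher than on the rest of the chromosome (Fisher exact p = 0.000385), so the excess was not spread over the whole chromosome. A difference in depth is not tied to position, so this comparison was no test of it. The Fisher test takes genes as independent, while neighbours may vary together and Abhd14a and Abhd14b overlap, so these p-values may be too small. The strain in which the locus was targeted is not given in the sources used here, and a direct effect of the altered locus on its neighbours was not tested.

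Per1 and Tsc22d3, genes induced by glucocorticoids, fell in Sema3b-/- arthritis (limma log2 fold change -1.74, adjusted p = 0.00301, and -1.06, adjusted p = 0.0148) and had values of 0.58 (adjusted p = 0.3) and 0.49 (adjusted p = 0.288) in WT. Their interaction values were -2.32 and -1.55, and neither was called. A different glucocorticoid response is a candidate explanation of the interaction, where of 13 other responsive genes 12 were negative, Fkbp5 at -0.01 among them (median -0.66, camera p = 0.000286, 0.0222 with an estimated correlation). Dusp1 (-0.86) is also on the immediate early list, which was itself negative in the interaction (camera adjusted p = 0.00602, not called with an estimated correlation). The shifts of these lists were not separated. Lower signalling in Sema3b-/- arthritis was not shown: the glucocorticoid list was higher in Sema3b-/- control (median 0.39, camera p = 0.00259, 0.051 with an estimated correlation) and had a median of -0.27 between arthritic genotypes (camera p = 0.107). Sex as the whole cause was argued against. With sex as a term the median of all 15 was 1.17 times its size without (-0.78), and that of the 13 others -0.72. However, 10 of these were negative and the list test was weaker (camera p = 0.0285, 0.156 with an estimated correlation). For time of day of sampling, clock genes of the evening and morning arms were 0.461 apart (medians 0.21 and -0.25). This gap lay between the bounds set for either reading and did not decide. Of the 7 evening genes 1 was negative in the interaction (range -0.15 to 0.60), where Per1 was at -2.32, and of 4 morning genes 3 were. The evening values argue against a sampling time that lowered these 7 genes along with Per1. A time effect on Per1 and Tsc22d3 without the evening arm was not tested.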

How the results depend on the processing

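The edgeR quasi-likelihood fits, TMM factors over all genes, pseudocounts, fits of 1 sex, a sex term for the lists and for the likeness of the arthritis effects, the fit without Sema3b among the genes tested and fits without libraries low in muscle or high in osteoblast RNA were chosen after the data were examined, and the other settings were planned. Of the single genes named, 11395 values under the alternatives were on the same side of the threshold with the same sign, 853 were no longer past it, 194 newly past it and 0 reversed. Unless given here, counts of genes and lists called in a comparison stayed within 1.5 times the value reported. Depth limits single genes most in Sema3b-/- control replicate 1, with 1732783 reads. The cause of the changes below was not tested, except that the log2 threshold can only lower a count. In females 1 WT arthritis library, and in males 1 Sema3b-/- arthritis library, is assumed to vary like the others.

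In WT arthritis the count of 582 was 1279 by DESeq2, 271 with the 2 groups alone, 196 with the replicate block, 229 without the 3 arthritis libraries of another title form, 380 with a term for title form, 133 with a sex term, 106 by edgeR with a sex term, 58 in females, 331 without the libraries low in muscle and epidermis and 189 at a log2 fold change of at least 1. Leaving out 1 library gave 149 (WT control replicate 3) to 1112 (WT arthritis replicate 2), with 188, 227 and 263 without WT control replicates 1, 2 and 4 and 300, 189 and 285 without WT arthritis replicates 3, 4 and 5.

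In Sema3b-/- arthritis 1710 became 998 with the 2 groups alone, 1020 with the block, 396 without the 3 libraries, 861 with the title term, 1025 in females, 0 in males (limma; 1374 at an unadjusted p under 0.05), 1130 without libraries low in muscle, 1045 without those high in osteoblast RNA and 798 at the log2 threshold. Leaving out 1 library gave 975 (Sema3b-/- arthritis replicate 2) to 1913 (WT arthritis replicate 1), with 995 without Sema3b-/- control replicate 3 and 1083 without Sema3b-/- arthritis replicate 5.

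Between control genotypes 2 calls became 5 by DESeq2, 1 without a filter, with the block, without the libraries high in osteoblast RNA and at the log2 threshold, and 0 by voom, at a CPM above 5, with the 2 groups alone, with a sex term, by edgeR with a sex term, with a pseudocount of 0.5, in females, without libraries low in muscle and with Sema3b left out of the genes tested. Leaving out 1 library gave 0 to 3 (WT arthritis replicate 2). Between arthritic genotypes 3 became 94 by DESeq2, 1 with the 2 groups alone, 0 without the 3 libraries, 9 by edgeR with a sex term, 203 in females and 0 in males; leaving out 1 library gave 2 (Sema3b-/- arthritis replicate 2) to 6 (WT arthritis replicate 4). The interaction, at 0, was 6 by DESeq2 and 6 in females, and 0 whichever library was left out.

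For WT control against Sema3b-/- arthritis 1491 became 2421 with the 2 groups alone, 932 with the block, 313 without the 3 libraries, 662 with the title term, 942 without libraries low in muscle and 692 at the log2 threshold, and 766 (WT control replicate 4) to 1717 (WT arthritis replicate 1) with 1 library left out; it was 915, 892 and 786 without WT control replicates 1, 2 and 3 and 834 without Sema3b-/- arthritis replicate 2. For Sema3b-/- control against WT arthritis 1253 became 7 with the 2 groups alone, 591 with the block, 700.0 without the 3 libraries, 242 in females, 6 in males, 643 without libraries high in osteoblast RNA and 457 at the log2 threshold, and 617 (Sema3b-/- control replicate 3) to 1834 (WT arthritis replicate 2) with 1 library left out; it was 766, 619 and 823 without WT arthritis replicates 3, 4 and 5.

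Sema3b between control genotypes, at -4.19, was no longer past the threshold by voom (-4.11), at a CPM above 5 (-4.19), with the 2 groups alone (-4.19), with a sex term (-4.20), by edgeR with a sex term (-3.95, adjusted p = 0.263, the highest), with a pseudocount of 0.5 (-4.57), in females (-4.29), without libraries low in muscle (-4.19) and without those high in osteoblast RNA (-4.29); with 1 library left out it was -4.66 (Sema3b-/- control replicate 4) to -3.65 (Sema3b-/- control replicate 1), and 9 of 18 ended the call. Between arthritic genotypes, at -4.48, it was not past the threshold without the 3 libraries (-4.14), in females (-3.44) and in males (-5.62).

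Lists called by camera numbered 16 in WT arthritis, 19 in Sema3b-/- arthritis, 8 and 10 between genotypes in control and arthritis, and 13 in the interaction. With an estimated correlation they were 0 in each, and with fry 5, 10, 0, 0 and 0. Without libraries high in osteoblast RNA 3 lists were called between control genotypes and 8 in the interaction. Leaving out 1 library gave 4 (Sema3b-/- control replicate 3) to 9 between control genotypes and 7 (WT arthritis replicate 3) to 14 in the interaction, with 8 without Sema3b-/- control replicate 2 or Sema3b-/- arthritis replicate 3. The correlation of 0.644 between the arthritis effects was 0.478 without the 3 libraries and 0.432 with a sex term. The 248 genes higher and 134 lower in both genotypes became 47 and 40 without the 3 libraries, 49 and 32 with a sex term and 492 and 236 by DESeq2. Sema3b, with a pseudocount of 5, was at -2.99 between control and -2.93 between arthritic genotypes.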

Other observations

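The genes of this part were chosen after their values were seen. Of 77 genes of ribosomal proteins, 52 rose in WT arthritis and 52 in Sema3b-/- arthritis by limma, and 0 fell, with medians of 0.50 and 0.48 where the medians of all genes were -0.02 and -0.01. With a sex term 26 and 47 rose. Of 7 clock genes of the evening arm, Nr1d1 (-1.80 in WT and -1.23 in Sema3b-/-), Dbp (-1.40 and -1.55), Tef (-1.21 and -1.0) and Per3 (-1.60 and -1.0) fell in both genotypes. Per2 (-1.12 and -0.66) fell in WT, and Hlf (-1.48 and -1.35) and Nr1d2 (-0.49 and -0.47) were not called. In the fit with a sex term Nr1d1 kept its limma call in WT (adjusted p = 0.0414), and Dbp (0.199), Tef (0.0864), Per3 (0.0719) and Per2 (0.145) did not, while in Sema3b-/- Hlf (0.037), Nr1d2 (0.0353) and, of the morning arm, Cry1 (0.00679) were called lower. The list medians were -1.40 and -1.0. Of the morning arm Npas2 was at 1.23 and 1.72 and rose in Sema3b-/-, while Arntl (0.15 and -0.01), Clock (0.01 and -0.33) and Cry1 (-0.13 and -0.76) were not called. The metallothioneins Mt1 (0.93 and 1.58) and Mt2 (1.05 and 1.93), paralogs whose shared reads were not examined, rose in both genotypes; with sex as a term they were at 0.98 (SE 0.24, adjusted p = 0.0571) and 1.1 (SE 0.31, adjusted p = 0.103) in WT, not called there with an error larger than 0.19 and 0.24 without that term. A2m, a protease inhibitor, fell by 4.06 in WT arthritis and Neat1, a nuclear noncoding RNA, by 1.42; in Sema3b-/- they were at -1.15 (adjusted p = 0.194) and -0.28 (adjusted p = 0.382). Both kept their limma calls in WT with sex as a term, at -3.92 (adjusted p = 0.0237) and -1.14 (adjusted p = 0.0357). No gene of this part was called by limma in the interaction, so none is shown to respond differently between the genotypes.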
